A study of Mus musculus with 9 samples.

How the data were processed

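RNA sequencing was read in 9 libraries of CD8+ T cells isolated from spleens of 6-week-old female C57BL/6 mice: 1 untreated, and 1 for each combination of IL-2 or IL-15, 1 or 500 nM and 4 or 24 h. Each library came from RNA of 3 identically treated samples pooled, and the labels name no cell sorting. Per the labels, 2.5 ng of RNA went through 12 and then 9 cycles of PCR, and fragments of 220 to 400 bp through 17 cycles, before sequencing on a HiSeq 2000. The submitters' processing notes give base calling with CASAVA 1.8 and alignment with Bowtie 0.12.4 to mm8. Strand use and the handling of multi-mapping reads are not given in the sources used here.

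The deposited files give raw read counts for 24373 RefSeq transcripts of 20418 gene symbols. They also give RPKM values which, per the file headers and the values, were made by the authors from the same counts, exon length and 1 total per library. Only counts were tested. For the 2673 symbols with more than 1 transcript, the transcript with the highest mean count was used. Of genes with at least 100 reads, 43 share their counts with another symbol and are marked as uncertain where named.

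Genes were kept by edgeR's filterByExpr (minimum count 10, total 15), which left 13479. Libraries were scaled by TMM, and edgeR 4.0.16 (quasi-likelihood, legacy deviances, R 4.3.3) fitted cytokine, dose and time as main effects with an untreated term over 9 libraries, leaving 4 residual degrees of freedom. Single interactions were tested by adding that term, leaving 3, and pairs of IL-15 and IL-2 at 1 dose and time with all 3 interactions of factor pairs, leaving 1. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Since no condition was repeated, the spread rests on the assumption that interactions left out of the model are small. Comparisons were IL-15 against IL-2 (over all conditions and at each dose), 24 h against 4 h, 500 nM against 1 nM, each time against untreated and the 3 interactions of factor pairs, all chosen before the data were examined. Dose at each time, each dose and time against untreated and the pair tests were added afterwards.

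The pipeline was tested on simulated data with 100 genes changed 2-fold and 100 changed 8-fold. Calls were 58 and 96 for dose, 68 and 96 for time, 24 and 87 for 4 h against untreated, 15 and 90 for 24 h against untreated, 35 and 80 for IL-15 against IL-2 at 1 nM, 44 and 88 at 500 nM, 11 and 78 for dose by time, and 5 and 59 for the pair at 1 nM and 24 h. Between 3 and 19 of 13279 unchanged genes were called. Simulated genes had no effect beyond the tested one, and their spread came from a fit with the dose by time term. In the real data the dose by time interaction enters the residual spread of the main-effects fit. It also enters that of the fits with a cytokine by dose or a cytokine by time term, which include IL-15 against IL-2 at each dose. Power in all these fits can be lower than the simulated counts.

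A total of 27 gene lists with 412 members, 408 of them measured, were fixed before the data were examined. They cover IL-2 and STAT5 targets, cytotoxic effectors, effector transcription factors, naive and memory genes, cytokine receptors, chemokines, costimulatory and inhibitory receptors, NK receptors, the BCL-2 family, S phase, mitosis, glycolysis, amino acid transport, cholesterol synthesis, ribosome biogenesis, ribosomal proteins, mitochondrial respiration, the unfolded protein response, interferon response, immediate early and heat shock genes, T cell identity, and markers of B, NK, myeloid, dendritic, CD4+ and erythroid cells. They were tested with camera of limma 3.58.1 (correlation preset 0.01), adjusted over all lists within a comparison. Matched libraries were compared without a test (at least 2-fold, the higher value at least 20 counts, offset 1), with list medians set against 10000 random lists drawn in 50 expression bins (seed 1). The random lists draw genes independently, so their percentiles ignore correlation between list members. Depth ran from 27158143 to 48799962 counts, which leaves a 0 in a transcript of 1 kb a limit of 0.0721 to 0.0420 RPKM, and the 10 highest genes took 7.99% to 13.9% of them.

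Named genes followed a rule set before the data were examined: per comparison, the 10 largest rises and 10 largest falls past the threshold with a mean of at least 20 counts in treated libraries and the same direction in every matched pair, or the 5 largest where fewer than 5 passed. Up to 4 members per list, 16 genes reported in every library and the 5 largest in each matched pair were added. Predicted genes without a standard symbol were counted but not named, and the text gives examples from each set. Some genes that the rule names are not reported here. Folds against 0 counts are lower bounds with a floor of 3 counts.

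Alternatives were DESeq2 1.42.0, limma-voom, median-of-ratios and quantile scaling, no filter, a mean of 50 counts, the mean over transcripts, folds of 1.5 and 3, levels of 5 and 100 counts, all interactions together, leaving out each treated library, camera with an estimated correlation, and fry. Sequence-level questions were left out because raw reads were not used here.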

Results

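RNA sequencing profiled CD8+ T cells from the spleens of 6-week-old female C57BL/6 mice that were left untreated or given interleukin-2 (IL-2) or interleukin-15 (IL-15). Both cytokines are growth factors for T cells and signal through shared receptor chains to the transcription factor STAT5, and the series asks how they come to act differently. Each was given at 1 nM or 500 nM for 4 h or 24 h, which made 8 treated libraries beside 1 untreated library. Every library came from RNA of 3 samples pooled, so no condition had a second library, and the tests below take their spread from the factorial layout. Counts with 1 transcript taken per gene summed to between 27158143 (IL-15, 1 nM, 4 h) and 48799962 (IL-2, 1 nM, 24 h) per library, over 12874 to 13238 genes with at least 1 read. A count of 0 in a transcript of 1 kb allowed a level of up to 0.0420 RPKM in the deepest library and 0.0721 RPKM in the shallowest. Intervals and limits cover counting error only, because PCR reads without molecular identifiers are not independent molecules, and p-values measure only the spread between these libraries.

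Across genes, each treated library was closest to the library of the other cytokine at the same dose and time, with r of 0.944 at 1 nM and 4 h, 0.944 at 1 nM and 24 h, 0.949 at 500 nM and 4 h and 0.970 at 500 nM and 24 h. The untreated library was closest to IL-15 at 1 nM and 24 h (r = 0.922). Genes are not independent replicates, so these values describe the libraries. Cd8a, the alpha chain of the CD8 co-receptor (NM_001081110, chromosome 6 of the mm8 build), was present in every library. It lay between 393 and 985 counts-per-million units (CPM), with 903 CPM untreated. Markers of other spleen cells were present too. In the untreated library the T cell identity genes summed to 6949 CPM, the B cell markers to 3026 CPM and the myeloid markers to 1186 CPM.

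The first comparison asked what raising the dose from 1 nM to 500 nM did, over both cytokines and both times (4 libraries against 4). At 500 nM the cells carried more mRNA for cytotoxic proteins, for STAT5 target genes and for interferon-induced genes, and less for genes of naive and memory T cells. Gzmb, which encodes the cytotoxic protease granzyme B, rose by 5.38 ± 0.76 (log2, SE), and Ifng, which encodes interferon gamma, rose by 6.16 ± 0.90. Lif, a cytokine gene on the STAT5 target list, rose by 6.65 ± 0.44 and was the largest rise among genes with more than a few counts at 1 nM. Il7r, the alpha chain of the IL-7 receptor, fell by 3.12 ± 0.45, and Tcf7, a transcription factor of naive and memory T cells, fell by 2.42 ± 0.18. Of 13479 genes tested, 1028 rose and 1142 fell at a false discovery rate (FDR) of 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2170 in all. Leaving out IL-2 libraries, the count was 1220 without 1 nM and 4 h, 1240 without 1 nM and 24 h and 976 without 500 nM and 24 h. It was 1025 without IL-15 at 1 nM and 24 h and 927 without IL-15 at 500 nM and 24 h. DESeq2 called 3495 genes, and the tests with a dose by time term and with all interactions called 4325 and 4621.

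The levels in single libraries show the range behind these averages. Gzmb (NM_013542, chromosome 14) measured 8.88 CPM in untreated cells. With IL-2 it measured 13.3 CPM at 1 nM and 4 h, 351 at 1 nM and 24 h, 934 at 500 nM and 4 h and 3683 at 500 nM and 24 h. With IL-15 the values in the same order were 18.3, 31.0, 1408.5 and 3489.7 CPM. Cish (NM_009895, chromosome 9), a feedback inhibitor induced by STAT5, measured 39.6 CPM untreated, between 36.5 and 268 CPM at 1 nM and between 1013 and 1626 CPM at 500 nM. Socs1, another feedback inhibitor of cytokine signalling, lay between 19.4 and 54.6 CPM at 1 nM and between 114 and 190 CPM at 500 nM, against 19.2 CPM untreated. Il2ra (NM_008367, chromosome 2), the high-affinity IL-2 receptor chain, measured 1.65 CPM untreated, 2.57 to 24.4 CPM at 1 nM and 35.9 to 88.8 CPM at 500 nM. Il2rb, the receptor chain that both cytokines use, went from 282 to 407 CPM at 1 nM to between 870 and 1096 CPM at 500 nM. Il15ra, the chain that binds IL-15, measured 17.2 CPM untreated, 4.49 to 26.1 CPM at 1 nM and 36.1 to 40.2 CPM at 500 nM. Prf1, which encodes the pore-forming protein perforin, was highest in the untreated library at 133 CPM and lay between 42.5 and 84.5 CPM in the treated ones. Myc, a growth-promoting transcription factor, measured 457 CPM untreated, 255 to 356 CPM at 1 nM and 674 to 1169 CPM at 500 nM.

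**Figure D1:**
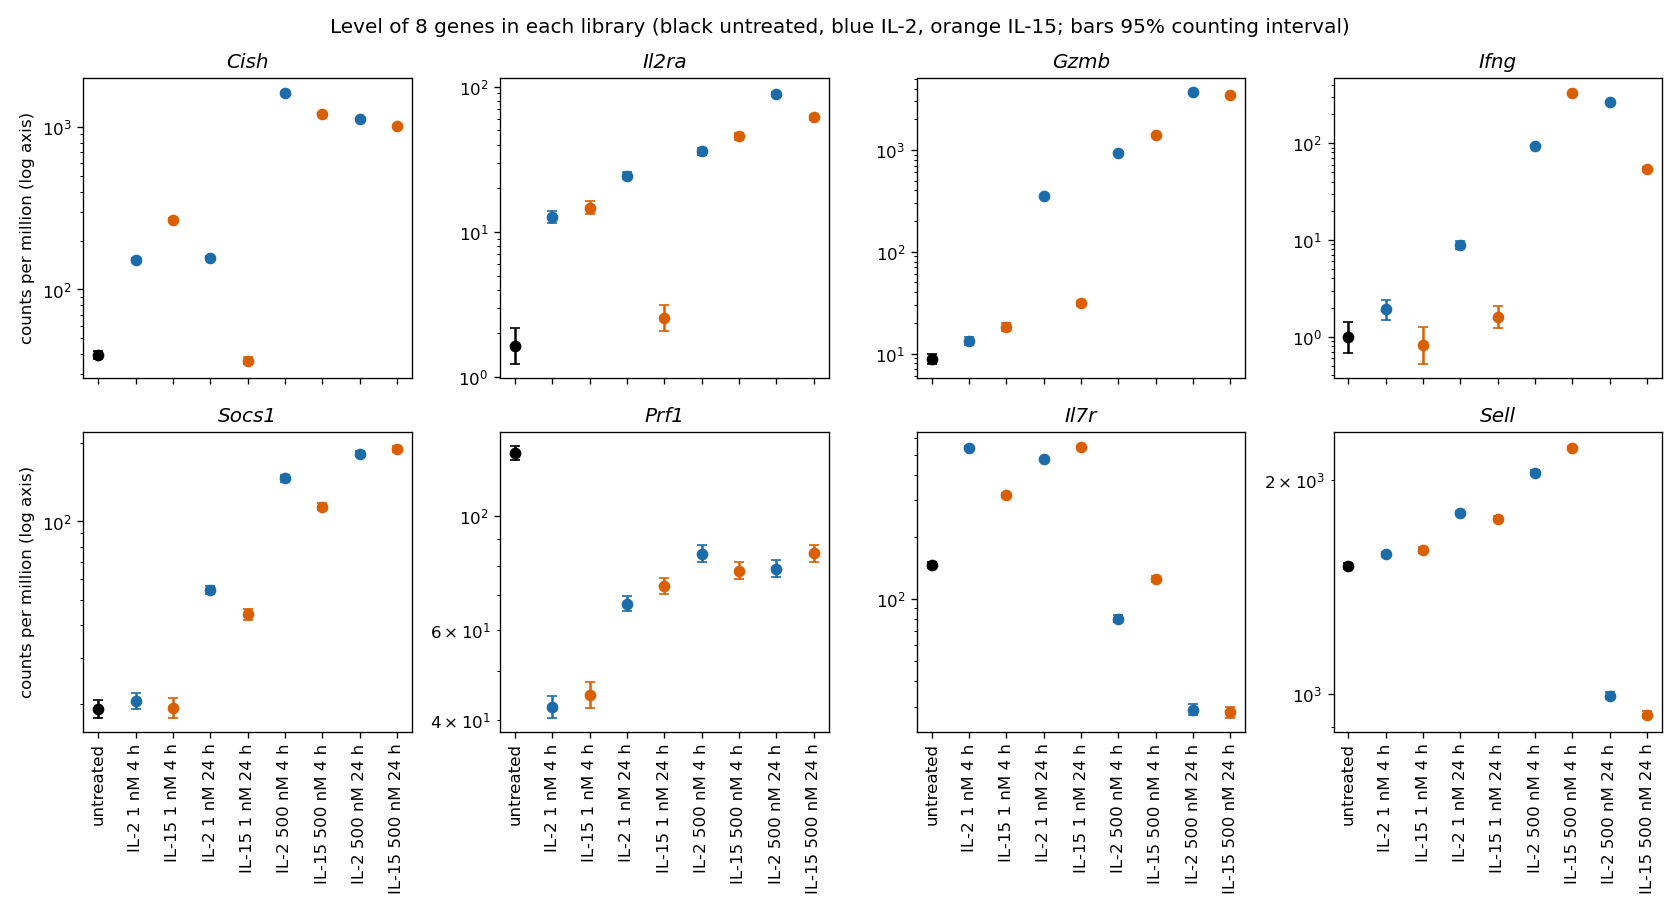
CPM (log axis) of 8 genes in each of the 9 libraries, one panel per gene, with bars for the 95% counting interval of that single library. Gzmb runs from 8.88 in the untreated library to 3683 with IL-2 at 500 nM and 24 h, while Il7r is lowest in the 500 nM libraries at 24 h (28.2 and 29.1).

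Of 17 measured IL-2 and STAT5 target genes, 14 rose with a median of 1.92 (16 adjusted over the list alone), with Lta at 3.85 ± 0.42, Osm at 3.78 ± 0.41 and Cish at 3.12 ± 0.43. Limma's camera test gave this list an adjusted p = 3.2e-15, and adjusted p = 0.15 with an estimated correlation. Of 21 interferon response genes, 19 rose with a median of 1.96 (21 adjusted over the list alone), among them Ifi44 at 3.27 ± 0.38, Gbp2 at 3.13 ± 0.65 and Isg15 at 3.12 ± 0.37 (camera adjusted p = 2.4e-15, adjusted p = 0.28 with an estimated correlation). Of 17 cytotoxic effector genes, 11 rose with a median of 2.91 (14 adjusted over the list alone), among them the granzyme genes Gzmc at 5.23 ± 0.65 and Gzmg at 5.07 ± 1.25 (camera adjusted p = 2.3e-10, adjusted p = 0.28 with an estimated correlation). Of 14 genes of naive and memory T cells, 9 fell with a median of -0.93 (11 adjusted over the list alone), among them S1pr1, a receptor for exit from lymphoid tissue, at -2.02 ± 0.29 and Klf2 at -2.00 ± 0.37 (camera adjusted p = 1.4e-08, adjusted p = 0.28 with an estimated correlation). Of 16 effector transcription factors, 6 rose and 1 fell, the same numbers adjusted over the list alone, with Eomes at 3.23 ± 0.33 and Tbx21 at 2.23 ± 0.31, both regulators of cytotoxic genes (camera adjusted p = 4.2e-04, adjusted p = 0.15 with an estimated correlation). Of 17 cytokine receptor chains, 7 rose and 3 fell (10 and 3 adjusted over the list alone), with the IL-12 receptor genes Il12rb1 at 4.06 ± 0.31 and Il12rb2 at 3.58 ± 0.62 and Il2ra at 2.13 ± 0.55 (camera adjusted p = 0.0053, adjusted p = 0.28 with an estimated correlation).

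Members of several metabolic and growth lists rose with dose, most of them in some lists and a minority in others. Of 16 amino acid transport and ATF4 target genes, 12 rose with a median of 1.67 (14 adjusted over the list alone), among them the amino acid transporter gene Slc7a5 at 2.46 ± 0.26 and Mthfd2 at 2.35 ± 0.24 (camera adjusted p = 6.3e-13, adjusted p = 0.074 with an estimated correlation). Of 22 ribosome biogenesis genes, 18 rose with a median of 1.03 (20 adjusted over the list alone), with Dkc1 at 1.42 ± 0.18 and Nolc1 at 1.40 ± 0.23 (camera adjusted p = 2.5e-11, adjusted p = 0.31 with an estimated correlation). Of 17 cholesterol biosynthesis genes, 7 rose with a median of 0.84 (12 adjusted over the list alone), with Idi1 at 1.86 ± 0.48 (camera adjusted p = 5.5e-06, adjusted p = 0.34 with an estimated correlation). Of 16 unfolded protein response genes, 5 rose with a median of 0.84 (13 adjusted over the list alone), with the chaperone gene Hspa5 at 1.54 ± 0.18 and Xbp1 at 1.32 ± 0.22 (camera adjusted p = 5.5e-06, adjusted p = 0.28 with an estimated correlation). Of 22 mitochondrial respiration genes, 7 rose with a median of 0.45 (10 adjusted over the list alone), led by the cytochrome c gene Cycs at 1.38 ± 0.23 (camera adjusted p = 2.8e-05, adjusted p = 0.35 with an estimated correlation). Of 15 glycolysis genes, 4 rose with a median of 0.77 (9 rose and 1 fell adjusted over the list alone), with Hk2 at 2.02 ± 0.43 and Eno1 at 1.51 ± 0.18 (camera adjusted p = 2.8e-04, adjusted p = 0.35 with an estimated correlation). Of 25 DNA replication and S phase genes 7 rose, with a median of 1.27 (16 adjusted over the list alone). Of 20 mitosis genes 4 rose, with a median of 1.52 (6 adjusted over the list alone), led by Tpx2 at 2.38 ± 0.59. Camera gave these adjusted p = 2.0e-07 and 5.2e-06, and both had adjusted p = 0.35 with an estimated correlation. Of 28 cytosolic ribosomal protein genes, 2 fell (0 adjusted over the list alone), Rpl19 at -0.69 ± 0.19 and Rplp1 at -0.55 ± 0.15, with a median of -0.37 (camera adjusted p = 3.6e-04, adjusted p = 0.34 with an estimated correlation).

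The remaining T cell lists showed single members moving rather than the whole list. Of 13 costimulatory and inhibitory receptors 3 rose (4 adjusted over the list alone), with Tnfrsf9, the 4-1BB receptor gene, at 2.75 ± 0.39, and the median of -0.26 differed in sign from the mean of 0.04 and from camera (upward, adjusted p = 0.55). Of 12 chemokine and chemokine receptor genes 3 rose (6 rose and 1 fell adjusted over the list alone), with Ccr2 at 2.18 ± 0.59 and Xcl1 at 1.99 ± 0.26 (median 0.57, camera adjusted p = 0.055). Of 8 NK receptors found on CD8+ T cells 1 rose (2 rose and 1 fell adjusted over the list alone), Klrc1 at 2.98 ± 0.69 (median 0.76, camera adjusted p = 0.26). Of 13 BCL-2 family genes 2 rose and 3 fell (3 and 3 adjusted over the list alone). The survival genes Bcl2l1 and Bcl2 stood at 1.70 ± 0.22 and 1.08 ± 0.28, and the death-promoting genes Bbc3 and Bmf at -1.74 ± 0.30 and -1.64 ± 0.28 (median 0.15, camera adjusted p = 0.78). Of 14 immediate early and heat shock genes 2 rose (4 adjusted over the list alone), led by Jun at 3.01 ± 0.28 (median 0.14, camera adjusted p = 0.063). Of 12 T cell identity genes 2 rose and 3 fell (3 and 4 adjusted over the list alone), with Cd8a at 0.71 ± 0.15 and Cd5 at -1.49 ± 0.24 (median -0.29, camera adjusted p = 0.49).

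Markers of other spleen cells moved with dose as well. Of 14 B cell markers 5 fell with a median of -0.94 (8 adjusted over the list alone), with Fcer2a at -2.06 ± 0.31 and Cd79b at -1.17 ± 0.22 (camera adjusted p = 4.0e-05, adjusted p = 0.34 with an estimated correlation). Of 12 myeloid markers 3 fell and 1 rose with a median of -2.74 (6 and 1 adjusted over the list alone, camera adjusted p = 0.0053, adjusted p = 0.38 with an estimated correlation). Among 6 erythroid markers 0 passed edgeR's test over all genes and 5 fell adjusted over the list alone, with a median of -1.44 (camera adjusted p = 0.0068, adjusted p = 0.28 with an estimated correlation). Of 8 dendritic cell markers 3 fell and 1 rose, the same numbers adjusted over the list alone, with Flt3 at -1.95 ± 0.51 and the interferon-inducible Bst2 at 2.22 ± 0.31 (median -0.95, camera adjusted p = 0.080). Of 7 NK cell markers 2 fell, also adjusted over the list alone, Tyrobp at -1.99 ± 0.39 and Fcer1g at -1.08 ± 0.28 (median -1.08, camera adjusted p = 0.18). Of 6 CD4+ and regulatory T cell markers 1 rose (1 rose and 1 fell adjusted over the list alone), Ikzf4 at 1.28 ± 0.29 (median -0.57, camera adjusted p = 0.78). The largest single falls included Mgst1 (-5.87 ± 1.13), Tnfsf13 (-5.43 ± 1.18) and Fam20c (-5.41 ± 1.01). Zscan10 had 0 counts in the 500 nM libraries and was at least 63.4-fold lower there. Dhh, with 2 counts over the 1 nM libraries, was 216-fold higher at 500 nM (95% counting interval 59.5 to 1793). Each gene named here as one of the largest changes moved the same way in all 4 matched pairs.

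The second comparison asked what changed between 4 h and 24 h of cytokine (4 libraries against 4). No library without cytokine is labelled 4 h or 24 h, so effects of longer cytokine and of longer culture cannot be told apart here. Some cell division and glycolysis genes were higher at 24 h, and some interferon-induced, heat shock and immediate early genes were lower. Cdc6, which loads the replicative helicase onto DNA, rose by 3.59 ± 0.69, and Rrm2, a subunit of ribonucleotide reductase, rose by 3.45 ± 0.83. The heat shock gene Hspa1a fell by 3.32 ± 0.36, and Il1r2, a decoy receptor for IL-1, fell by 4.61 ± 0.48. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 362 genes rose and 353 fell, 715 in all. The count depended on single libraries. For IL-2 it was 214 without 1 nM and 4 h, 351 without 1 nM and 24 h, 117 without 500 nM and 4 h and 168 without 500 nM and 24 h, and for IL-15 in the same order it was 1328, 1150, 198 and 82. DESeq2 called 2126 genes and limma-voom 1234, the test with a dose by time term 3045, and the test without both 1 nM libraries of 24 h called 3715.

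Of 25 DNA replication and S phase genes 6 rose with time (21 adjusted over the list alone) with a median of 1.59. Of 20 mitosis genes 6 rose (18 adjusted over the list alone) with a median of 1.99. Among them were Ccnb1, the cyclin B1 gene, at 2.92 ± 0.61 and Bub1 at 2.75 ± 0.63. Camera gave adjusted p = 3.2e-12 and 7.2e-10, and both had adjusted p = 0.38 with an estimated correlation. Of 15 glycolysis genes 5 rose with a median of 0.97 (11 adjusted over the list alone), with Tpi1 at 2.21 ± 0.45, Eno1 at 1.22 ± 0.18 and Ldha at 1.19 ± 0.27 (camera adjusted p = 1.8e-07, adjusted p = 0.38 with an estimated correlation). Of 21 interferon response genes 7 fell with a median of -1.08 (12 adjusted over the list alone), with the antiviral genes Rsad2 at -3.19 ± 0.51, Mx2 at -3.16 ± 0.57 and Ifit1 at -2.57 ± 0.38 (camera adjusted p = 5.6e-08, adjusted p = 0.38 with an estimated correlation). Of 14 immediate early and heat shock genes 8 fell with a median of -1.72 (11 fell and 1 rose adjusted over the list alone), with Hspa1b at -3.01 ± 0.42 and Fos at -2.32 ± 0.28 (camera adjusted p = 1.1e-09, adjusted p = 0.24 with an estimated correlation). Of 16 effector transcription factors 3 fell (3 fell and 1 rose adjusted over the list alone), Nr4a1 at -2.55 ± 0.17, Nr4a2 at -1.99 ± 0.28 and Irf4 at -1.73 ± 0.22, all early-response genes of T cell activation (camera adjusted p = 0.0059, adjusted p = 0.29 with an estimated correlation). Of 12 T cell identity genes 3 rose with a median of 0.37 (5 adjusted over the list alone), with Cd5 at 1.33 ± 0.24, Lat at 1.08 ± 0.18 and Thy1 at 0.84 ± 0.15 (camera adjusted p = 1.9e-04, adjusted p = 0.25 with an estimated correlation). Erythroid markers had a median of -1.82, with 2 of 6 lower (4 adjusted over the list alone), the globin genes Hbb-b1 and Hbb-b2, which share their counts and cannot be told apart (camera adjusted p = 5.6e-04, adjusted p = 0.32 with an estimated correlation). Of 14 B cell markers 3 fell and 1 rose, the same numbers adjusted over the list alone, with a median of -0.57 (camera adjusted p = 0.028, adjusted p = 0.54 with an estimated correlation). Of 8 dendritic cell markers 1 fell (3 fell and 1 rose adjusted over the list alone), Itgax at -1.79 ± 0.30, with a median of -1.04 (camera adjusted p = 0.047, adjusted p = 0.38 with an estimated correlation).

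Among the largest changes with time were genes of division and of macrophages. Nuf2, a kinetochore gene (4.05 ± 0.64), Anln (3.94 ± 0.62) and Stil (3.98 ± 0.94) rose. So did Marco, a macrophage scavenger receptor gene (3.78 ± 0.73), and Gpnmb, a gene of lipid-laden macrophages (5.52 ± 0.51). Gpnmb measured 24.6 and 42.4 CPM in the 1 nM libraries of 24 h and at most 1.76 CPM in the 500 nM libraries, and Marco measured 200 CPM with IL-2 and 201 CPM with IL-15 at 1 nM and 24 h against at most 20.8 CPM in the other treated libraries. Ptges had 0 counts at 4 h and was at least 94.3-fold higher at 24 h, and Cd207, the langerin gene, had 0 counts at 24 h and was at least 111-fold lower there. Gng4 (-5.48 ± 1.05), Itgad (-3.62 ± 0.48) and Slc45a3 (-3.50 ± 0.80) also fell.

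Whether the dose effect differed between the times was tested as an interaction over 8 treated libraries. Most S phase and mitosis genes rose more with dose at 24 h than at 4 h, and some interferon genes rose less. The median S phase gene stood at 0.03 (IL-2) and 0.17 (IL-15) above the untreated library at 500 nM and 4 h, and at 3.02 and 2.87 at 500 nM and 24 h. The median interferon gene stood at 3.32 and 4.25 at 500 nM and 4 h, and at 1.71 and 2.09 at 500 nM and 24 h. Mki67, the gene of the proliferation marker Ki-67, had an interaction of 3.61 ± 0.55 and Rrm2 one of 3.67 ± 0.59. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 547 genes had a larger and 641 a smaller dose effect at 24 h. The total of 1188 was 369 without IL-2 at 500 nM and 24 h. It was 400 without IL-15 at 1 nM and 4 h, 781 without IL-15 at 1 nM and 24 h, 602 without IL-15 at 500 nM and 4 h and 356 without IL-15 at 500 nM and 24 h, and DESeq2 called 1792.

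Of 25 S phase genes 22 had a positive interaction (23 adjusted over the list alone), with a median of 2.32. Of 20 mitosis genes 14 did (17 adjusted over the list alone), with a median of 2.63. Camera gave adjusted p = 3.2e-15 and 1.2e-10, and both had adjusted p = 0.32 with an estimated correlation. Of 15 glycolysis genes 7 had a positive interaction (8 adjusted over the list alone) with a median of 1.19 (camera adjusted p = 1.1e-06, adjusted p = 0.32 with an estimated correlation). Of 21 interferon genes 7 had a negative one (16 adjusted over the list alone) with a median of -1.52 (camera adjusted p = 3.8e-05, adjusted p = 0.59 with an estimated correlation). Of 12 myeloid markers 6 had a negative interaction (9 adjusted over the list alone) with a median of -2.88, among them the lysozyme gene Lyz2 at -6.14 ± 0.34 and its relative Lyz1 at -5.87 ± 0.41 (camera adjusted p = 4.0e-07, adjusted p = 0.32 with an estimated correlation). Lyz2 measured 138 CPM with IL-2 and 217 CPM with IL-15 at 1 nM and 24 h, 2.04 and 2.82 CPM at 500 nM and 24 h, and 20.9 CPM untreated. Tested at each time alone, a comparison chosen after the data were seen, dose changed 1355 genes at 4 h (731 higher, 624 lower) and 4207 genes at 24 h (2103 higher, 2104 lower) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At 4 h the count was 690 without IL-2 at 1 nM, 831 without IL-15 at 1 nM and 567 without IL-15 at 500 nM. At 24 h it was 2086 without IL-2 at 500 nM, 2437 without IL-15 at 1 nM and 2176 without IL-15 at 500 nM.

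The third comparison set the treated libraries of each time against the untreated library. After 4 h, some interferon response, STAT5 target and amino acid genes were higher than in untreated cells, and some T cell identity genes were lower. Lif rose by 6.55 ± 0.88, Cish by 3.81 ± 0.82 and Asns, the asparagine synthetase gene, by 4.40 ± 0.72. The transporter gene Slc16a5 fell by 4.17 ± 0.24 and Dtx1, a regulator of Notch signalling, by 4.09 ± 0.37. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 119 genes rose and 208 fell at 4 h (327 in all). DESeq2 called 810 higher and 556 lower and limma-voom 142 and 535, so the balance of rises and falls depends on the tool. The edgeR total was 48 without IL-2 at 1 nM and 4 h and 176 without IL-15 at 500 nM and 4 h. At 24 h 9 rose and 37 fell (46 in all), DESeq2 called 707 higher and 364 lower, and limma-voom 12 and 237. The edgeR total was 25 without IL-2 at 1 nM and 4 h, 30 without IL-15 at 1 nM and 4 h and 202 without IL-15 at 1 nM and 24 h. With a dose by time term the totals were 1667 and 1438. All comparisons against untreated share 1 library, so any peculiarity of that library enters each of them. The labels give it no time, and no library without cytokine is labelled 4 h or 24 h. Effects of cytokine and of time in culture therefore cannot be told apart in the comparisons against untreated, as in that of 24 h with 4 h.

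At 4 h, 4 of 21 interferon response genes rose (18 adjusted over the list alone) with a median of 2.64, with Ifit1 at 4.14 ± 0.75 and Isg15 at 3.70 ± 0.70 (camera adjusted p = 1.9e-12, adjusted p = 0.34 with an estimated correlation). Of 17 STAT5 target genes 3 rose with a median of 1.13 (8 adjusted over the list alone, camera adjusted p = 2.1e-06, adjusted p = 0.29 with an estimated correlation). Of 16 amino acid and ATF4 genes 4 rose with a median of 1.12 (9 adjusted over the list alone, camera adjusted p = 1.4e-06, adjusted p = 0.18 with an estimated correlation). Of 12 T cell identity genes 3 fell with a median of -0.62 (6 adjusted over the list alone), Cd5 at -2.04 ± 0.33, Lat at -1.50 ± 0.26 and Zap70 at -1.04 ± 0.22 (camera adjusted p = 4.9e-05, adjusted p = 0.18 with an estimated correlation). Pdcd1, the inhibitory receptor PD-1, rose by 3.34 ± 0.48, and Cd160 fell by 3.30 ± 0.53. Il1r2, with 1 count in the untreated library, was 268-fold higher at 4 h (95% counting interval 48.1 to 10605). At 24 h Lif (6.63 ± 0.89), Ly6a (4.28 ± 0.62), Socs1 (2.33 ± 0.36) and Cdkn1a, the p21 cell cycle inhibitor (3.54 ± 0.55), were among the 9 genes that rose. The 37 that fell included genes of myeloid cells: Csf1r, the receptor for macrophage colony-stimulating factor (-5.23 ± 0.81), Itgad (-6.54 ± 0.59) and Plbd1 (-4.35 ± 0.28). Cd207 was at least 309-fold lower. Myeloid markers had a median of -2.18 at 4 h and -2.14 at 24 h, and dendritic cell markers one of -2.01 and -1.98. Camera gave the myeloid list adjusted p = 0.0035 and 3.0e-04 (adjusted p = 0.61 and 0.42 with an estimated correlation) and the dendritic cell list adjusted p = 0.0035 and 8.4e-06 (adjusted p = 0.29 and 0.20 with an estimated correlation).

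Split by dose, which was chosen after the data were seen, the counts against untreated by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 850 genes at 1 nM and 4 h, 222 at 1 nM and 24 h, 2209 at 500 nM and 4 h and 3391 at 500 nM and 24 h. The first was 283 without IL-2 at 1 nM and 4 h and 476 without IL-15 at 1 nM and 4 h, and the second 93 without IL-2 at 1 nM and 24 h. The third was 1070 without IL-15 at 500 nM and 4 h, and the fourth 1840 without IL-2 and 1800 without IL-15 at 500 nM and 24 h. At 500 nM and 24 h, 23 of 25 S phase genes rose (25 adjusted over the list alone) with a median of 2.96. Of the mitosis genes 18 of 20 rose (19 adjusted over the list alone) with a median of 3.52, and 21 of 22 ribosome biogenesis genes rose (22 adjusted over the list alone) with a median of 1.48. Of 14 B cell markers 13 fell, also adjusted over the list alone, with a median of -1.94. Of 12 myeloid markers 8 fell and 1 rose (10 and 1 adjusted over the list alone) with a median of -3.99. At 1 nM and 24 h, Il7r was higher than in untreated cells (475 and 543 CPM against 146), and Tbx21 fell by 1.66 ± 0.23. The lysozyme genes Lyz2 and Lyz1 rose by 3.06 ± 0.31 and 2.84 ± 0.37, and Csf1r fell by 3.41 ± 0.42.

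**Figure D2:**
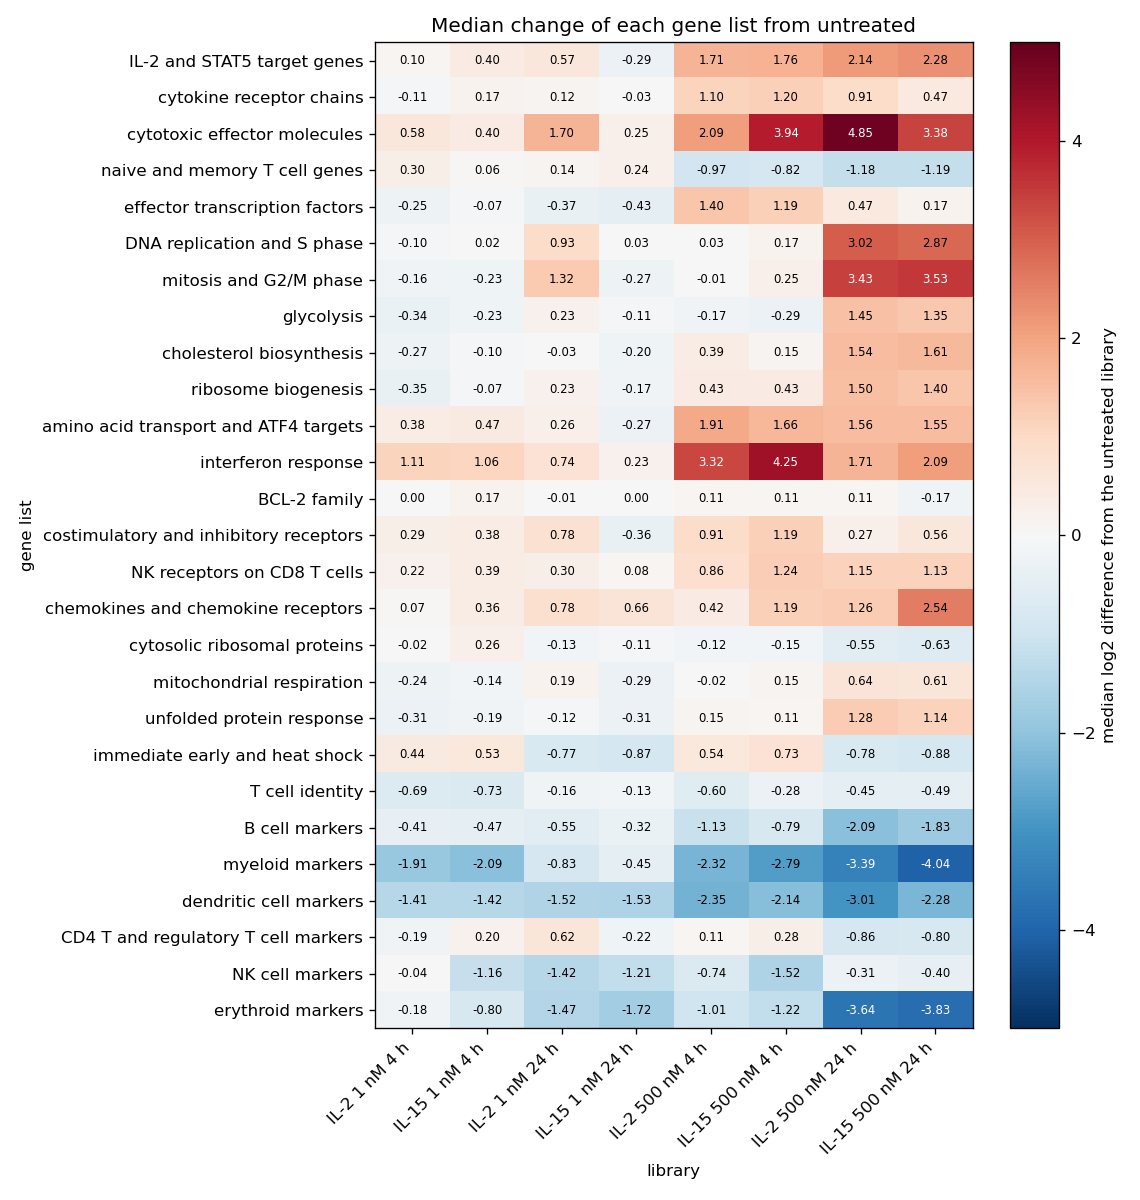
Median log2 difference from the untreated library for each of the 27 gene lists (lines) in each of the 8 treated libraries (columns), with higher medians in red and lower ones in blue. The S phase and mitosis lists have medians of 2.87 to 3.53 at 500 nM and 24 h, while the myeloid list is below 0 in all 8 libraries.

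The central question of the series was where IL-15 and IL-2 differ. Averaged over doses and times (4 libraries against 4), no gene passed. Several of the larger average differences were in genes of low level: Tle6 stood at 3.08 ± 0.96 and Gpr56 at 3.04 ± 1.32 in favour of IL-15, and the milk protein genes Wap and Csn2 at -4.62 ± 1.21 and -3.85 ± 0.89. Within 1 nM the 5 largest differences towards IL-2 included Il22, an effector cytokine gene, and at 500 nM the milk genes Glycam1 and Wap. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 0 of 13479 genes passed, with 125 at an unadjusted p under 0.05 and a smallest adjusted p of 1. DESeq2 called 2 genes, limma-voom 0, and the test with all interactions in the model 3. Within 1 nM edgeR called 0 genes (193 unadjusted, 7 by DESeq2) and within 500 nM 0 (81 unadjusted, 6 by DESeq2). The cytokine by dose and cytokine by time interactions had 0 calls each by edgeR (151 and 189 unadjusted) and 0 by DESeq2 and limma-voom.

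Fewer genes than the 5% that chance gives had an unadjusted p under 0.05. The dose by time interaction enters the residual spread of the test over all conditions, which can make it conservative. It also enters that of the tests within each dose and of the cytokine interactions. Few genes were also called with all interactions in the model, as given above. In that fit the dose by time interaction does not enter the residual spread, but only 1 residual degree of freedom is left. Whether the interaction accounts for the whole shortfall in unadjusted p-values stays open. In simulated data without that interaction, the test over all conditions called 67 of 100 genes changed 2-fold and 93 of 100 changed 8-fold. Among the lists, the amino acid and ATF4 targets lay lower with IL-15 over all conditions by a median of -0.17 (camera adjusted p = 0.010, adjusted p = 0.96 with an estimated correlation), and at 500 nM by -0.20 (camera adjusted p = 0.044, adjusted p = 0.98 with an estimated correlation). At 500 nM the interferon list lay higher with IL-15 by a median of 0.69 (camera adjusted p = 1.2e-07, adjusted p = 0.98 with an estimated correlation), and by -0.01 without IL-15 at 500 nM and 4 h. At 1 nM the mitosis list lay lower with IL-15 by a median of -0.68 and the cytotoxic list by -0.41 (camera adjusted p = 0.0025 and 0.043, each adjusted p = 0.97 with an estimated correlation). The S phase list (-0.34), the interferon list (-0.39) and the immediate early and heat shock list (-0.41) also lay lower and the ribosomal protein list higher (0.10), with camera adjusted p = 0.037, 0.024, 0.037 and 0.037, each adjusted p = 0.97 with an estimated correlation. Leaving out 1 library turned 4 of the 6 lists, to 0.29 for mitosis without IL-15 at 1 nM and 24 h and to 0.26 for cytotoxic and 0.39 for interferon genes without IL-2 at 1 nM and 24 h, and S phase to 0.48 without IL-15 at 1 nM and 24 h and 0.29 without IL-2 at 1 nM and 4 h. Within each of these lists edgeR called 0 genes over all genes, and adjusted over the list alone it called 1, a mitosis gene lower with IL-15 at 1 nM.

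Matched pairs show where the cytokines were furthest apart, as differences between single libraries with no replicate check. The number of genes at least 2-fold apart was 1666 at 1 nM and 4 h, 1669 at 1 nM and 24 h, 1560 at 500 nM and 4 h and 827 at 500 nM and 24 h. By comparison, dose pairs differed in 2694 to 4624 genes and time pairs in 2263 to 3738. At 1 nM and 24 h the medians of response and division lists lay lower with IL-15 than with IL-2. Gzmb measured 31.0 CPM with IL-15 (95% counting interval 29.3 to 32.8) against 351 with IL-2 (345 to 356), Cish 36.5 against 156, Il2ra 2.57 against 24.4 and Ifng, the interferon gamma gene, 1.61 against 8.85. Socs1 lay closer, at 44.2 against 54.6 CPM. Some members went the other way, among them Prf1 (73.0 CPM with IL-15 against 67.5 with IL-2). The STAT5 target genes Mcl1 (300 against 202), Pim1 (7.37 against 5.80) and Socs3 (183 against 168) did so too. The median mitosis gene differed by -1.52, the cytotoxic list by -1.15, the S phase list by -0.89, the STAT5 target list by -0.76 and the interferon list by -0.60, each below all of 10000 random lists matched on expression. T cell identity genes differed by 0.04 (percentile 77.6) and myeloid markers by 0.06 (percentile 64.5). Percentiles here and below ignore correlation between list members, so they can overstate how unusual a shift of co-regulated genes is.

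At 500 nM and 4 h the order was the other way for interferon and effector genes. Ifng measured 331 CPM with IL-15 (95% counting interval 325 to 337) against 93.1 with IL-2 (89.9 to 96.5). The interferon list lay higher with IL-15 by a median of 0.93 and the cytotoxic list by 0.57, at percentiles of 100 and 99.98. After 24 h at 500 nM, Ifng measured 54.5 CPM with IL-15 against 265 with IL-2, Gzmb 3489.7 against 3683 and Cish 1013 against 1115, while the STAT5 target list differed by -0.21 (percentile 0.01) and the interferon list by 0.38 (percentile 100). At 1 nM and 4 h the STAT5 target list lay higher with IL-15 by 0.32 (percentile 99.6), with Bcl2, the survival gene, at 508 CPM against 180 and Cish at 268 against 152. The largest folds in each pair were of genes with 0 counts in 1 library, such as Gata1, with 230 counts for IL-2 and 0 for IL-15 at 1 nM and 24 h, Serpine2 (96 for IL-15 and 0 for IL-2 in the same pair), Spata7 at 1 nM and 4 h (179 for IL-2 and 0 for IL-15) and Pdia5 at 500 nM and 4 h (93 for IL-15 and 0 for IL-2).

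**Figure D3:**
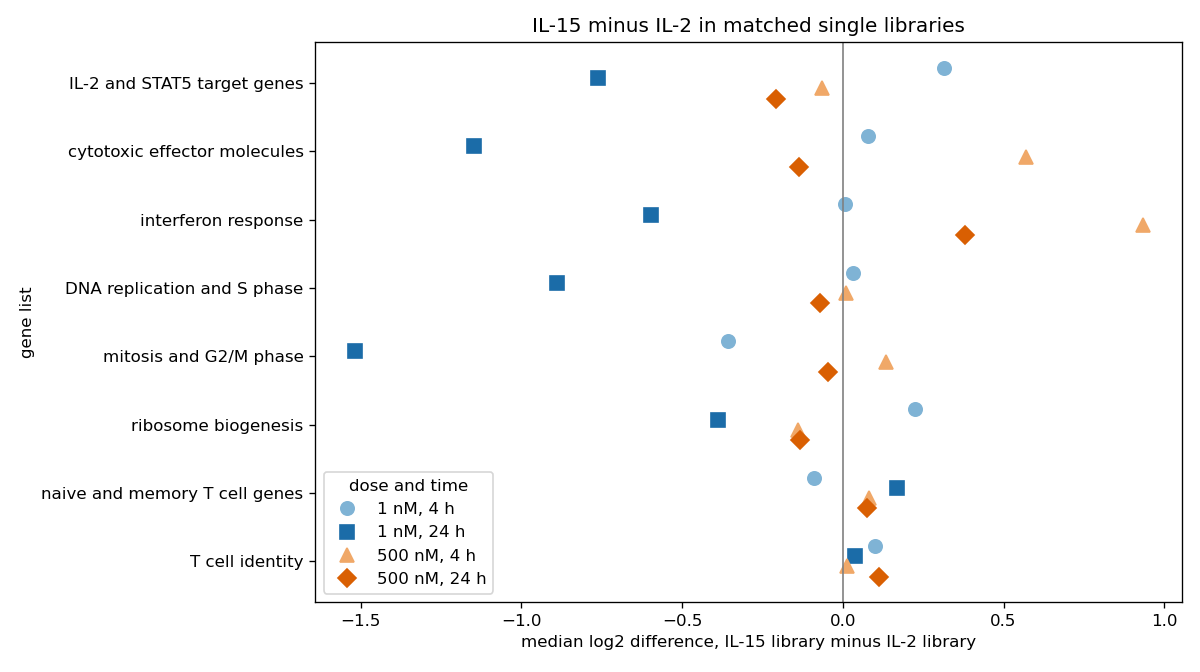
Median IL-15 minus IL-2 difference (log2) of 8 gene lists at each of the 4 dose and time settings, each point a difference between 2 single libraries. At 1 nM and 24 h the mitosis list lies at -1.52 and the T cell identity list at 0.04, and at 500 nM and 4 h the interferon list lies at 0.93.

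A test of each pair, chosen after the data were seen, used a model with all 3 interactions of factor pairs, which left 1 residual degree of freedom. Its fitted folds borrow from the other libraries and so differ from the ratios of the pair itself, which were 11.3-fold for Gzmb and 5.50-fold for Ifng at 1 nM and 24 h. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 59 genes differed at 1 nM and 24 h (2 higher and 57 lower with IL-15), 14 at 500 nM and 4 h (11 higher, 3 lower), 2 at 1 nM and 4 h (both lower) and 0 at 500 nM and 24 h (364 unadjusted, 0 by DESeq2 and limma-voom). At 1 nM and 24 h the genes lower with IL-15 included Ifng (-3.17 ± 0.40), Gzmb (-2.68 ± 0.43), the division genes Shcbp1 (-4.74 ± 0.78), Zwilch (-3.45, a kinetochore gene) and Mcm10 (-2.64, a replication factor), and the interferon-induced Iigp1 (-2.94). Of 20 mitosis genes 4 fell (13 adjusted over the list alone) with a median of -1.32, and of 21 interferon genes 5 fell (13 adjusted over the list alone) with a median of -0.59. Camera gave adjusted p = 4.9e-10 and 2.6e-09, and both had adjusted p = 0.74 with an estimated correlation. At 500 nM and 4 h the genes higher with IL-15 included Cxcl10, an interferon-induced chemokine (1.63 ± 0.29), Mx1 (1.63), Oasl2 (1.48) and Oas2 (1.31). Of 21 interferon genes 3 rose (18 adjusted over the list alone) with a median of 1.01 (camera adjusted p = 3.2e-15, adjusted p = 0.98 with an estimated correlation). DESeq2 called 62 genes at 1 nM and 24 h, 53 of them shared. With median-of-ratios scaling the 3 counts above 0 became 19, 0 and 0 in the order given, and with quantile scaling all were 0. With bias-adjusted deviances all were 0 too, but that fit called 0 of 100 genes changed 8-fold in simulated data for the pair at 1 nM and 24 h (59 by the fit used here), so it says nothing about that pair. Each condition had 1 library, so differences of preparation between the libraries of a pair enter these counts.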

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

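Each result in this part stood out because an effect differed between groups of libraries by a test of the difference itself (an interaction term), except the milk gene and the IL-15 patterns weighed below, which were picked out of the values per library. The tests of dilution, of a smaller T cell share and of Cish, the interval used as spread for the milk gene correlations, and the repeat without Mfge8 and Xdh were chosen only after the result was seen. The effect of dose differed between 4 h and 24 h for 1188 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Among genes with a larger dose effect at 24 h, the named ones were Cyb561 (10.75), Slc36a4 (8.33), Prr11 (8.07), Hbegf (7.11), Aspm (6.27), Hmmr (6.07), Tex9 (5.81), Tnip3 (5.46), Kif24 (5.38) and Polq (4.86). Prr11, Aspm, Hmmr and Kif24 act in cell division and Polq in DNA repair. Among genes with a smaller or opposite dose effect at 24 h, they were Crispld2 (-13.98), the milk casein gene Csn1s2a (-12.16), Rnase4 (-11.20), Epb4.1l1 (-10.37), Ift81 (-10.32), Kcnj10 (-10.28), the lipid regulator Pparg (-9.66), Fabp4 (-9.19), and the macrophage receptor genes Fcgr1 (-8.94) and Mrc1 (-8.83). Where a group of libraries has 0 counts, such fitted values depend on the prior count and mark direction rather than size. Marco (-3.34) and Slc45a3 (-4.10), already named for dose or time, differed too.

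By limma's camera test the dose effect of the lists was larger at 24 h for S phase (median interaction 2.32), mitosis (2.63), glycolysis (1.19), cholesterol biosynthesis (0.88), ribosome biogenesis (0.76), mitochondrial respiration (0.60) and unfolded protein response genes (0.82). It was smaller or more negative for cytotoxic (-1.16), naive and memory (-0.74), interferon (-1.52), B cell (-1.10), myeloid (-2.88) and erythroid genes (-1.80). The difference between IL-15 and IL-2 changed with dose for cytotoxic (0.86), mitosis (0.57) and interferon genes (1.19), though on leaving out 1 library the first became -0.16 (without IL-2 at 1 nM and 24 h) and the second -0.34 and -0.48 (without IL-15 at 24 h and 1 nM or 500 nM). It changed with time for STAT5 target (-0.72), cytotoxic (-0.89), interferon (-0.82) and mitochondrial respiration genes (-0.24), with interferon at 0.20 without IL-2 at 1 nM and 24 h and -0.05 without IL-15 at 500 nM and 4 h. None of these list calls passed with an estimated correlation between members.

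The first pattern weighed is the lower level of myeloid genes at 500 nM than at 1 nM after 24 h. Library depth was excluded, since the median myeloid fold, from depth-scaled counts with an offset of 1, was -3.55 after thinning every library to 27158143 counts and -3.52 before. Plain dilution by more T cells does not account for the whole fall if B cell markers gauge it. In edgeR's fitted folds, which are larger for low counts than those with the offset, the median was -4.44 for myeloid and -1.41 for B cell markers. The difference was -3.03 (permutation p = 2.0e-04). The permutation moved genes between the lists, so its p-value measures no spread between libraries. Whether B cell markers changed for reasons of their own was not tested. A smaller share of macrophages fits: 23 macrophage genes not looked at before lay lower at 500 nM by a median of -2.69. The direction held for 23 of 23, and 17 passed an FDR of 0.05 by edgeR's test. A change of state within macrophages and an effect of the dose on macrophage survival stay open and were not tested.

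The second pattern is the lower level of response and division genes with IL-15 than with IL-2 at 1 nM after 24 h. A smaller share of T cells was excluded for the whole fall only. T cell identity genes differed by a median of 0.038 (quartiles -0.05 and 0.16), where the STAT5 target list fell by a median of -0.76. Identity genes themselves lay lower at the higher dose after 24 h, so a small difference in share could be masked. Their medians against untreated were -0.16 (IL-2) and -0.13 (IL-15) at 1 nM, and -0.45 and -0.49 at 500 nM. Depth was excluded, since the STAT5 target median was -0.72 after thinning. The prediction for a weaker response was met: 798 genes raised by dose at 4 h had a median of -0.34 (percentile 0 of random lists). Of these, 77.2% lay below 0, and 684 genes lowered by dose had a median of 0.28. Members of the response lists were not removed from these sets. The test therefore largely restates the pattern and does not decide on its cause. After 24 h at 500 nM the 798 genes had a median of -0.00, while the 684 still had one of 0.12 (percentile 100). Less active IL-15 in that culture, faster loss of it and a different potency of the cytokines at low dose stay open and were not tested, since the condition had 1 library.

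The third pattern is milk protein mRNA. Csn2, Wap and other milk genes summed to 13.7 CPM untreated, to 3.55, 25.6, 9.33 and 2.63 CPM with IL-2 (1 nM at 4 h and 24 h, then 500 nM at 4 h and 24 h) and to 0.906, 3.57, 0.321 and 0.0593 CPM with IL-15 in the same order. Expression driven by the cytokine signal was taken to need rho above 0.5 between the sum and Cish across the 9 libraries. The value was rho = -0.40 (interval -0.84 to 0.36, permutation p = 0.291, BH 0.437 over 3 relations), with r = -0.32 (permutation p = 0.434, BH 0.651, -0.44 without the 2 farthest libraries). This argued against expression that rises with Cish. At 500 nM Cish was similar with IL-2 and IL-15 (1626 and 1192.5 CPM at 4 h, 1115 and 1013 CPM at 24 h). The relation therefore cannot decide on a signal of 1 cytokine alone, which was not tested. Reads from mammary gland libraries cannot be told apart from other sources. Csn2 followed 11 other mammary genes with rho = 0.28 (interval -0.47 to 0.80, permutation p = 0.463, BH 0.463; r = 0.17, permutation p = 0.699, BH 0.699, 0.10 without the 2 farthest libraries), which met the bound set in advance against this source but within its spread, and Mfge8 and Xdh held nearly all of those counts. A repeat without these, on 9 genes, gave rho = 0.68 (interval 0.03 to 0.93, permutation p = 0.0537, BH 0.161) and r = 0.87 (permutation p = 0.0064, BH 0.0193), which fell to 0.11 without the 2 farthest libraries.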

How the results depend on the processing

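The model with a dose by time term, the one without both 1 nM libraries of 24 h, bias-adjusted deviances, dose at each time, each dose and time against untreated and the IL-15 and IL-2 pair tests were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the labels link no library of one condition to an animal or preparation of another. Of 238 called results for named genes, 238 kept direction and threshold with no filter, 230 by DESeq2, 224 with median-of-ratios scaling, 224 with the mean over transcripts, 211 with quantile scaling, 179 with bias-adjusted deviances and 174 by limma-voom. On leaving out each library in turn, 1237 of 1744 such values kept both and 507 fell below the threshold; no named gene reversed. Pseudocounts, planned for normalized values, were not run for the tests on counts; for matched pairs, offsets of 0.1 and 5 kept every count within 1.5 times its value, and the pair tests had no leave-one-out. Leaving out 1 library left the IL-15 against IL-2 counts and their interactions at 0 to 0. The other ranges were 82 to 1328 (time), 927 to 2435 (dose), 48 to 328 and 25 to 202 (4 h and 24 h against untreated), 356 to 1102 (dose by time), 567 to 1561 and 2086 to 4384 (dose at 4 h and 24 h), 283 to 1010, 93 to 305, 1070 to 2397 and 1800 to 3630 (against untreated at 1 nM 4 h, 1 nM 24 h, 500 nM 4 h and 500 nM 24 h) and 92 to 118 for list calls.

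DESeq2 called 2 genes for IL-15 against IL-2, 7 at 1 nM, 6 at 500 nM, 40 in the pair at 500 nM and 4 h, 2126 for time, 3495 for dose, 1792 for dose by time, 1366 and 1071 for 4 h and 24 h against untreated, and 1359 and 728 for 1 nM at 4 h and 24 h against untreated. Limma-voom called 1234 for time, 677 and 249 for 4 h and 24 h against untreated, and 0, 19 and 0 in the pairs at 1 nM 4 h, 1 nM 24 h and 500 nM 4 h. All interactions in the model gave 3 for IL-15 against IL-2, 3500 for time and 4621 for dose. Bias-adjusted deviances gave 1092 for time, 505 and 182 against untreated and 0, 0 and 0 in those pairs, where simulated 8-fold changes (tried at 1 nM 24 h) gave 0 calls as well; the dose by time term 3045 for time, 4325 for dose and 1667 and 1438 against untreated; the model without both 1 nM libraries of 24 h 3715 for time and 1841 and 2380 against untreated. Median-of-ratios gave 0, 19 and 0 in the pairs, quantile scaling 0, 0 and 0 and 75 for 24 h against untreated, the mean over transcripts 1 and a mean of 50 counts 35 at 500 nM and 4 h. Of 91 list calls 0 remained with an estimated correlation; fry called 44 lists, 34 of them among the 91. Matched IL-15 and IL-2 pairs (1 nM 4 h, 1 nM 24 h, 500 nM 4 h, 500 nM 24 h) held 891, 900, 850 and 437 genes with a mean of 50 counts, 3361, 3303, 3175 and 1746 at 1.5-fold, 895, 908, 817 and 409 at 3-fold, 703, 721, 607 and 218 at 100 counts, and 1474 in the last pair at 5 counts. The changed level or fold threshold explains these matched pair counts by construction. For the rest the cause was not tested.

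Lists that reversed did so for IL-15 against IL-2 on leaving out 1 library. At 1 nM their medians ran from -1.09 to 0.26 for cytotoxic genes (highest without IL-2 1 nM 24 h) and from -1.55 to 0.48 for S phase (highest without IL-15 1 nM 24 h, 0.29 without IL-2 1 nM 4 h). They ran from -2.53 to 0.29 for mitosis (highest without IL-15 1 nM 24 h) and from -0.96 to 0.39 for interferon (highest without IL-2 1 nM 24 h). In the interaction with dose they ran from -0.16 (without IL-2 1 nM 24 h) to 1.57 for cytotoxic genes and from -0.48 to 2.63 for mitosis (-0.34, without IL-15 1 nM 24 h). In that with time they ran from -1.46 to 0.20 for interferon (highest without IL-2 1 nM 24 h; -0.05 without IL-15 500 nM 4 h, where camera's direction reversed). The remaining library of a pair is taken to vary like the others.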

Other observations

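In the 1 nM libraries of 24 h, some macrophage genes were higher than in the untreated library and others were lower. The fixed myeloid list lay below untreated there, with medians of -0.83 (IL-2) and -0.45 (IL-15). Cd5l, a gene of tissue macrophages, measured 296 CPM with IL-2 and 381 with IL-15 there, against 77.0 CPM untreated. Cd68 measured 38.6 and 41.7 CPM there, 5.38 and 3.89 CPM at 500 nM and 24 h and 21.1 CPM untreated. Axl measured 35.5 and 55.0 CPM, then 8.47 and 10.2 CPM, and was higher in the untreated library than in any of these, at 337 CPM. These 3 genes were chosen after their values were seen.

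The tests of other splits were set before the result was seen. For IL-15 against IL-2 the test is void, since the real count of 0 makes 33 of 33 splits of the 8 treated libraries at least as large by construction. The largest count, 1390, followed the dose by time interaction and so reflects the structure of the samples. For time 1 of 33 splits was as large as the real 715 genes (highest other 2), and for dose 1 of 33 was as large as the real 2170 (highest other 0). In the other splits the real time or dose effect was left out of the model and entered the residual spread. Low counts were therefore favoured in advance, and no conclusion is drawn from these splits.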
